A study of Mus musculus with 6 samples.

How the data were processed

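RNA of sorted S1 and S3 cells was amplified with the Ovation system and tagged with biotin, and each of 6 samples was hybridised to an Affymetrix mouse whole-genome expression array, per the labels and the series' design text. Signals were computed with MAS5 and normalized to 18S ribosomal RNA, Gapdh and beta-actin probe sets, per the series' design text. The version of MAS5 and its scaling target are not given in the sources used here. The deposited values are log2 signals. Values reach below 0, and in each array the median of the 3 reference probe sets' deviations from their medians over arrays is 0, where the design text speaks of an average. The base of the logarithm is not stated, and 2 was taken from the size of MAS5 signals. The plan had assumed linear values; the deposited log2 values were used as they are, with no further log and no added constant.

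Of 45101 probe sets, 64 were controls, 34958 had 1 gene symbol, 932 several and 9211 none in the platform annotation. Only probe sets with 1 symbol were named, and 34754 probe sets had a gene identifier in the reference gene table (assembly GRCm38.p6), which changed 0 symbols and was used for names only. No coordinates are given, since the array's annotation names no build. List members without a probe set of their own single symbol are not analysed here.

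Arrays were grouped by their titles. The number of arrays limits the precision, and no detection calls were used. Background was therefore set, after seeing the data, at the 95th percentile per array of 27 control probe sets for bacterial transcripts (log2 1.01 to 1.74). A gene not above it on any array of a subset is given as an at-least fold: the brighter subset's mean against the dimmer subset's mean of, per array, the higher of background and its own value. Tested genes had a mean log2 signal above the 40th percentile of all non-control probe sets, with the brightest probe set taken per gene, which left 11959. None of 5765 genes with several tested probe sets had probe sets called in opposite directions. For 42 called and named genes with 77 other tested probe sets, 76 of these had the same sign and 41 were also called.

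S3 minus S1 was fitted with limma 3.58.1 (R 4.3.3; lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There were 4 residual and 3.41 prior degrees of freedom. Changes are log2 differences with their standard errors. 26 gene lists were fixed before the data were examined, and the 24 with at least 3 measured genes were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. camera sets each list against all other genes, so a list it calls higher or lower moved up or down relative to those genes. The median of all genes fell, so such a higher list need not have risen in S3. "Relative to all genes" means minus the median log2 change of all genes tested.

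Named genes followed a rule fixed before the data were examined: the 10 largest rises and 10 largest falls among called genes whose subsets do not overlap and whose brighter subset lies in the upper 50% of probe sets, up to 4 called members of each list with the smallest p (the 2 smallest where none was called), and a set of genes named in advance. Tdg of that set is not analysed here, and another item is not reported here. A gene that several parts of the rule name counts under each.

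Alternatives planned before the data were examined were median centring, quantile normalization, a common 2% trimmed mean (in place of the reference division, already made), no filter and a 60th percentile filter, the 25th percentile of linear values added before log2, no intensity trend, a robust trend, the mean over a gene's probe sets, the replicate number as a block and leaving out each array. Alternatives added after seeing the data were a block for short and long arrays (actin 5' minus 3' below or above -1.5), that difference as a covariate, this block with median centring, and the short or the long arrays alone.

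The fits were tested on simulated arrays with the genes' own means and spread, 11959 genes and 200 changed ones. For S3 minus S1, 12% of genes changed by a log2 difference of 1 and 36% of those changed by 2 were recovered, with 4 false among 52 calls. With the class block these shares were 48% and 79%, with 12 false among 139 calls. The simulation changed fewer genes than were called in the data (1835, or 5617 with the class block). Its cut on the unadjusted p was therefore stricter, and these shares do not give the sensitivity in the data. Camera called 0 of 24 unchanged simulated lists. The simulation took only means and spread from the data, not the correlation between genes of a list. In the data that correlation, estimated per list, ran from -0.14 (macrophage markers) to 0.76 (embryonic globins). The simulated lists therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes.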

Results

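Gene expression was measured in 2 subsets of red cell precursors sorted from mouse fetal liver, named S1 and S3, each with 3 arrays. Livers of Balb/C embryos were dissociated, and cells were stained for CD71 (the transferrin receptor), Ter119 (a red cell surface antigen) and lineage markers and sorted by flow cytometry. S1 holds the less mature cells of this scheme and S3 more mature ones. Each subset was sorted on 3 separate days, per the series' design text, so that the 3 arrays of a subset are biological replicates. The labels disagree on embryo age: the stage label gives embryonic day 12.5 for S1 and 13.5 for S3, and the source label gives 13.5 for all 6 arrays. A difference in embryo age between the subsets is therefore not excluded for any value below. Values are the authors' log2 signals, scaled to 3 reference probe sets, and the number of arrays limits their precision. The profiles were made for work on global loss of DNA methylation in red cell formation.

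The median log2 signal of an array lay between 1.83 and 2.94. Pearson's r between arrays, across the upper 60% of probe sets by mean signal (probe sets are not independent replicates), was 0.901 to 0.965 within a subset and 0.844 to 0.919 between subsets. Arrays also differed in how far their signal reached toward the 5' end of a transcript. In the actin control, the 5' probe set read lower than the 3' probe set by a log2 difference of -2.08 in S1 replicate 1, -2.59 in S1 replicate 2 and -2.20 in S3 replicate 2. That difference was only -0.47 in S1 replicate 3, -0.45 in S3 replicate 1 and -0.56 in S3 replicate 3. The former 3 arrays are called short and the latter 3 long, and each subset holds both kinds. The first component of the deviations from the subset means held 65.0% of the variance within subsets and separated short from long arrays.

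**Figure D1:**
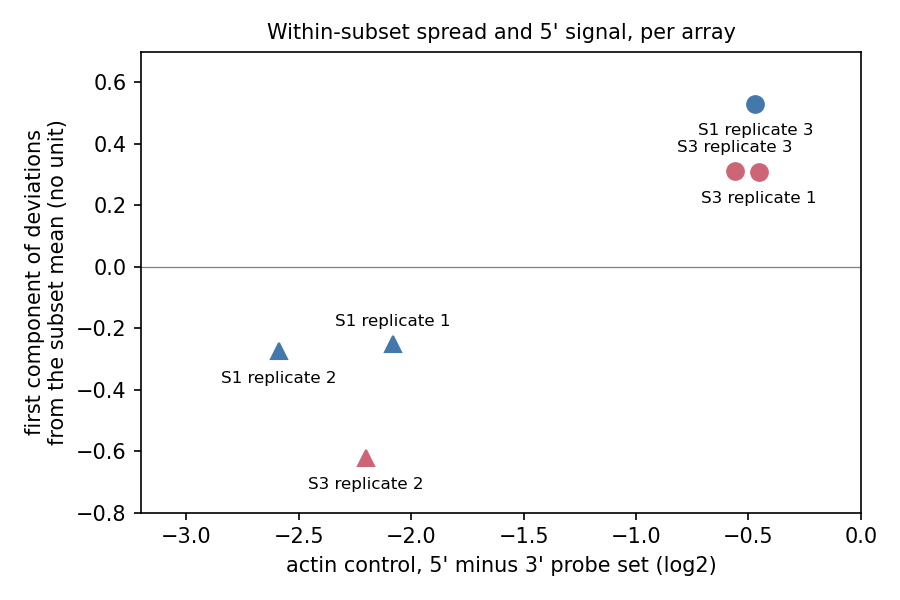
First component of each array's deviations from its subset mean (vertical axis, no unit) against the log2 difference between the 5' and 3' probe sets of the actin control (horizontal axis), with 1 point per array, blue for S1, red for S3, circles for long and triangles for short arrays. The 3 short arrays lie between -0.62 and -0.25 on the component and the 3 long arrays between 0.31 and 0.53.

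The comparison of S3 with S1 asked which genes differ between these stages. Several progenitor regulators were lower and several red cell products higher in S3. Kit, the receptor for stem cell factor, fell from 7.68 ± 0.85 in S1 to 0.84 ± 0.15 in S3 (mean log2 signal ± SD, n = 3 arrays each), where no array was above background. Myb, a transcription factor of progenitors, fell from 10.43 ± 0.07 in S1 to 6.86 ± 0.09 in S3 (log2 change -3.57 ± 0.17 (SE), adjusted p = 0.00103). In the opposite direction, Alas2, the first enzyme of heme synthesis in red cells, rose from 5.51 ± 0.88 in S1 to 10.39 ± 0.27 in S3 (log2 change 4.88 ± 0.45 (SE), adjusted p = 0.00279), and Slc4a1, the band 3 anion exchanger, rose from 8.84 ± 0.60 in S1 to 11.29 ± 0.07 in S3 (log2 change 2.45 ± 0.27 (SE), adjusted p = 0.00315). That S3 reading of Slc4a1 lay close to the highest among gene probe sets (11.66). Dimmer probe sets of Slc4a1 (mean 9.78 and 3.62) changed by 2.87 ± 0.42 and 3.88 ± 0.86 (SE). Of 11959 genes tested with limma, 302 were higher and 1533 lower in S3 at an adjusted p under 0.05, and 258 and 1264 of them differed at least 2-fold. At this scale the median log2 change of all genes was -0.33. Centring each array on its median moved it to 0.04 and gave 595 higher and 771 lower genes, or 43.6% higher against 16.5%. Quantile normalization gave 695 and 1127 (38.1% higher) and a common trimmed mean 612 and 1138 (35.0% higher). With the short and long arrays as a block, chosen after seeing the data, 695 genes were higher and 4922 lower, and this block with median centring gave 2488 and 1808 (57.9% higher). Counts of list members under the class block, given below, stand against these 695 and 4922 of 11959 genes. Within the long arrays alone (1 S1, 2 S3) the counts were 617 and 4151, and within the short arrays alone (2 S1, 1 S3) 337 and 2601, each lone array being assumed to vary like the others. Single arrays moved the counts. There were 136 higher and 541 lower genes without S1 replicate 1, 147 and 608 without S1 replicate 2, and 370 and 897 without S1 replicate 3. There were 128 and 823 without S3 replicate 1, and 119 and 675 without S3 replicate 3. The median log2 change was -0.14 without S1 replicate 3 and -0.15 without S3 replicate 2. Every S3 array lay on one side of every S1 array for 4219 genes (35.3%, where chance gives 10% on average over splits). All genes share the same 6 arrays, so the share of a single split can lie far from 10% by chance.

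**Figure D2:**
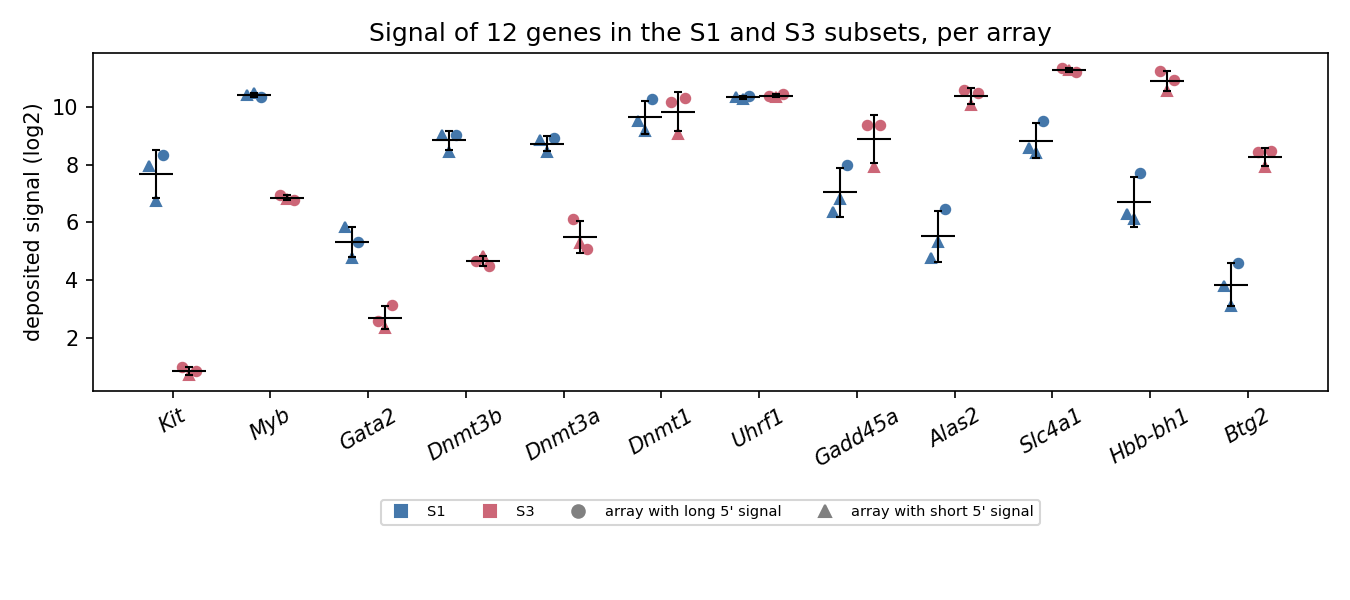
Deposited log2 signal (vertical axis) of 12 genes (horizontal axis) in each of 3 S1 arrays (blue) and 3 S3 arrays (red), with circles for long and triangles for short arrays. Horizontal bars and whiskers are the mean ± SD of a subset; the S3 arrays of Kit, Myb, Gata2, Dnmt3b and Dnmt3a all lie below the S1 arrays, those of Alas2, Slc4a1, Hbb-bh1 and Btg2 all above, and those of Dnmt1, Uhrf1 and Gadd45a overlap them.

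By fitted log2 change, an order that rests partly on values under background, the 10 named risers were Fn3k (fructosamine 3-kinase), Rragd (a Rag GTPase of mTORC1 signalling), Cfap57, Krt15 (a keratin), Ackr3 (an atypical chemokine receptor), Tnfrsf13c, Runx1t1 (a transcriptional corepressor), Tinagl1, Apol11b and Ncf4 (a subunit of the phagocyte NADPH oxidase). Runx1t1 (log2 change 5.99 ± 0.40 (SE), adjusted p = 0.00252), Apol11b (5.56 ± 0.43, adjusted p = 0.00252) and Ncf4 (5.50 ± 0.59, adjusted p = 0.00307) read above background on all 6 arrays. Cfap57 and Tnfrsf13c were not above background on any S1 array and were at least 51.9-fold and 13.4-fold higher in S3 (adjusted p = 0.00310 and 0.00420). Fn3k (8.97 ± 1.27, adjusted p = 0.00570), Rragd (8.36 ± 1.27, adjusted p = 0.00705) and Tinagl1 (5.57 ± 0.92, adjusted p = 0.00937) were above background on 1 S1 array, and Krt15 (6.89 ± 1.49, adjusted p = 0.0228) and Ackr3 (6.85 ± 0.61, adjusted p = 0.00279) on 2. With values raised to background these 5 log2 changes were 7.24, 6.49, 5.01, 5.95 and 6.26. The 10 named fallers, ordered the same way, were Adamts3 (a metalloprotease), Kit, Rgs19 (a regulator of G protein signalling), Syde2, St8sia4 (a polysialyltransferase), Trib2 (a pseudokinase), Sox4 (a transcription factor), Cep55 (a protein of cell abscission), Slain1 and Def6. Trib2 was above background on every array (log2 change -6.22 ± 0.36 (SE), adjusted p = 0.00192). Kit, Syde2, St8sia4 and Slain1 were not above background on any S3 array and were at least 86.7-fold, 31.5-fold, 27.6-fold and 29.0-fold lower in S3 (adjusted p = 0.00252, 0.00271, 0.00315 and 0.00302). Adamts3 (-7.57 ± 0.97, adjusted p = 0.00450) and Def6 (-5.84 ± 1.07, adjusted p = 0.0129) were above background on 1 S3 array, and Rgs19 (-6.41 ± 1.43, adjusted p = 0.0252), Sox4 (-6.02 ± 1.26, adjusted p = 0.0209) and Cep55 (-6.00 ± 1.27, adjusted p = 0.0215) on 2. With values raised to background these 5 were -5.49, -4.53, -5.14, -4.81 and -4.65. Krt15 missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00361 to 0.0829, the highest without S1 replicate 1). Rgs19 missed the threshold in 5 of 16 other planned fits (adjusted p from 0.00370 to 0.0904, the highest without S1 replicate 1). Sox4 missed the threshold in 2 of 16 other planned fits (adjusted p from 0.00423 to 0.0751, the highest without S1 replicate 1). Cep55 missed the threshold in 2 of 15 other planned fits (adjusted p from 0.00370 to 0.0787, the highest without S1 replicate 1). Def6 missed the threshold in 2 of 15 other planned fits (adjusted p from 0.00496 to 0.0623, the highest without S1 replicate 1).

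Of 15 measured progenitor factors and receptors, 7 fell in S3, none rose and 8 were not called (7 lower and 0 higher adjusted over the list alone). Besides Kit, Myb and Sox4, these were Hhex (log2 change -3.39 ± 0.48 (SE), adjusted p = 0.00570), Cbfa2t3 (-1.70 ± 0.29, adjusted p = 0.0102), Gata2 (-2.62 ± 0.46, adjusted p = 0.0115) and, outside the naming rule and chosen after its values were seen, Fli1 (-2.33 ± 0.46, adjusted p = 0.0163). The list's median log2 change was -1.37 relative to all genes. camera called the list lower (adjusted p = 0.00418, or adjusted p = 0.397 with an estimated correlation). With the class block 11 members were lower. Spi1, a myeloid transcription factor, was not called (log2 change -0.80 ± 0.64 (SE), adjusted p = 0.491). Cbfa2t3 missed the threshold in 1 of 16 other planned fits (adjusted p from 0.00895 to 0.0837, the highest with median centring). Gata2 missed the threshold in 1 of 16 other planned fits (adjusted p from 0.00955 to 0.0530, the highest without S1 replicate 1). Fli1 missed the threshold in 4 of 16 other planned fits (adjusted p from 0.0134 to 0.0637, the highest without S1 replicate 1).

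Both de novo DNA methyltransferases fell in S3 and the maintenance enzyme was not called. Dnmt3b fell from 8.85 ± 0.34 in S1 to 4.67 ± 0.17 in S3 (log2 change -4.18 ± 0.33 (SE), adjusted p = 0.00252) and Dnmt3a from 8.73 ± 0.26 in S1 to 5.50 ± 0.56 in S3 (-3.24 ± 0.37, adjusted p = 0.00341). The sizes depended on the probe set. The 4 dimmer probe sets of Dnmt3a changed by -2.61 to -1.04, with 2 of them called, and the mean of its probe sets by -2.33 (limma adjusted p = 0.0355). The dimmer probe set of Dnmt3b changed by -3.10 ± 0.57. Dnmt1, which copies methylation after replication, read 9.66 ± 0.57 in S1 and 9.85 ± 0.69 in S3 (0.20 ± 0.40, adjusted p = 0.809), and its partner Uhrf1 10.35 ± 0.06 in S1 and 10.40 ± 0.05 in S3 (0.05 ± 0.08, adjusted p = 0.783). The sign for Dnmt1 turned with the class block (-0.16, adjusted p = 0.337) and differed between its probe sets. Of 20 measured genes of DNA methylation and demethylation, 5 fell, 0 rose and 15 were not called. One gene was higher and 5 lower adjusted over the list alone, and 1 higher and 6 lower had an unadjusted p under 0.05. The other 3 that fell were Zbtb38, a methyl-CpG binding protein (log2 change -3.28 ± 0.53 (SE), adjusted p = 0.00875), Hells, a chromatin remodeller (-1.18 ± 0.21, adjusted p = 0.0113), and, outside the naming rule and chosen after its values were seen, the uracil glycosylase Ung (-0.99 ± 0.21, adjusted p = 0.0226). Tet2 (-1.49 ± 0.50, adjusted p = 0.0915) and Gadd45a (1.85 ± 0.55, adjusted p = 0.0612) were not called over the 6 arrays. Under the class block both passed (Tet2 -1.83, adjusted p = 3.00e-04, Gadd45a 1.38, adjusted p = 1.34e-04), as they did with median centring and with quantile normalization; the trimmed mean called only Gadd45a of these. Over all other planned fits the adjusted p was 0.0429 to 0.216 for Tet2 and 0.00206 to 0.189 for Gadd45a. Tet1 (-0.90 ± 0.55, adjusted p = 0.343), Tet3 (0.04 ± 0.72, adjusted p = 0.979) and Mbd4 (0.46 ± 0.69, adjusted p = 0.736) were not called. Dnmt3l was too dim to be tested. With the class block 1 gene of the list was higher and 8 lower. Under that block 4922 of all 11959 genes were lower, and the list's median was -0.22 relative to all genes. The list as a whole was not called by camera (adjusted p = 0.360, or adjusted p = 0.815 with an estimated correlation). Hells missed the threshold in 3 of 16 other planned fits (adjusted p from 0.00946 to 0.158, the highest with the mean of its probe sets). Ung missed the threshold in 8 of 16 other planned fits (adjusted p from 0.0174 to 0.508, the highest with median centring).

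All 3 embryonic globin genes were higher in S3. The arrays read pooled sorted cells, so a change within maturing cells and a different mix of cells cannot be told apart here. Hbb-bh1 went from 6.70 ± 0.88 in S1 to 10.92 ± 0.35 in S3 (log2 change 4.22 ± 0.43 (SE), adjusted p = 0.00302), Hba-x from 7.34 ± 1.17 in S1 to 10.93 ± 0.05 in S3 (3.59 ± 0.51, adjusted p = 0.00589) and Hbb-y from 9.46 ± 1.12 in S1 to 11.51 ± 0.05 in S3 (2.05 ± 0.48, adjusted p = 0.0299). In S3 these readings lay close to the highest of the array (11.66 among gene probe sets). A dimmer probe set of Hbb-y (mean 9.22) changed by 3.78 ± 0.72 (limma adjusted p = 0.0193 over probe sets). Another (mean 10.48) changed by 2.13 ± 0.50. Of the adult globin list 2 genes were measured and neither was called, while 1 had an unadjusted p under 0.05: Hba-a2 (1.02 ± 0.31, adjusted p = 0.0657, read at 9.35 ± 0.61 in S1 and 10.36 ± 0.30 in S3) and Hbb-b2 (0.01 ± 0.07, adjusted p = 0.951, read at 10.80 ± 0.08 in S1 and 10.81 ± 0.05 in S3, also near the top). A dimmer probe set of Hbb-b2 (mean 6.40) changed by 1.23 ± 0.45 (adjusted p = 0.138 over probe sets). Hba-a2 passed with the class block (0.79, adjusted p = 0.00407) and in 5 of 16 other planned fits: the 3 other scalings and those without S1 replicate 3 or S3 replicate 2 (adjusted p from 0.00636 to 0.179 over the 16). Of 20 genes of heme synthesis and iron uptake, 6 rose and 1 fell (10 and 2 adjusted over the list alone), and 13 were not called. Risers besides Alas2 included the mitochondrial iron importer Slc25a37 (1.61 ± 0.17, adjusted p = 0.00307), Ppox, an enzyme of heme synthesis (1.39 ± 0.16, adjusted p = 0.00352), and Abcb10, a mitochondrial transporter (1.00 ± 0.12, adjusted p = 0.00359, with 1 of its 2 other probe sets of opposite sign). Fech (0.69 ± 0.08, adjusted p = 0.00377) and Urod (0.39 ± 0.10, adjusted p = 0.0395), enzymes of heme synthesis named outside the rule after their values were seen, also rose. The faller, outside the naming rule and chosen after its values were seen, was the heme exporter Flvcr1 (-1.70 ± 0.38, adjusted p = 0.0242). Tfrc, the transferrin receptor used in the sort, was not called (0.21 ± 0.10, adjusted p = 0.200, read at 10.65 ± 0.16 in S1 and 10.86 ± 0.03 in S3, also near the top). Dimmer probe sets of Tfrc (mean 9.99 and 7.82) changed by 0.42 ± 0.11 and 1.77 ± 0.66 (limma adjusted p = 0.0562 and 0.149 over probe sets). Of 19 genes of the red cell membrane and skeleton, 10 rose, none fell and 9 were not called (11 higher adjusted over the list alone), among them the dematin gene Dmtn (2.95 ± 0.45, adjusted p = 0.00744), Gypc (0.94 ± 0.14, adjusted p = 0.00630) and Icam4 (1.03 ± 0.17, adjusted p = 0.00988). camera called embryonic globins (adjusted p = 1.21e-05, or adjusted p = 0.356 with an estimated correlation), heme and iron genes (adjusted p = 1.18e-08, or adjusted p = 0.356 with an estimated correlation) and membrane genes (adjusted p = 4.35e-11, or adjusted p = 0.356 with an estimated correlation) higher. The class block gave 10 higher and 4 lower heme and iron genes and 12 higher and 1 lower membrane genes. Hbb-y missed the threshold in 4 of 16 other planned fits (adjusted p from 0.0114 to 0.0870, the highest without S3 replicate 3). Abcb10 missed the threshold in 1 of 16 other planned fits (adjusted p from 8.40e-04 to 0.214, the highest with the mean of its probe sets). Fech missed the threshold in 2 of 16 other planned fits (adjusted p from 0.00229 to 0.130, the highest with median centring). Urod missed the threshold in 9 of 16 other planned fits (adjusted p from 0.0221 to 0.330, the highest with no intensity trend). Flvcr1 missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00747 to 0.0840, the highest without S1 replicate 2). Icam4 missed the threshold in 1 of 16 other planned fits (adjusted p from 0.00787 to 0.0712, the highest with median centring).

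Of 14 erythroid transcription factors 3 rose, none fell and 11 were not called (4 higher and 1 lower adjusted over the list alone). The risers were E2f2 (log2 change 3.28 ± 0.37 (SE), adjusted p = 0.00325), Nfe2 (1.83 ± 0.24, adjusted p = 0.00484) and Tal1 (0.59 ± 0.14, adjusted p = 0.0300). Gata1 (-0.12 ± 0.15, adjusted p = 0.668), whose sign turned under each other scaling, and Klf1 (0.44 ± 0.34, adjusted p = 0.479) were not called. camera called the list higher (adjusted p = 6.06e-05, or adjusted p = 0.356 with an estimated correlation). The erythropoietin receptor gene Epor read 6.55 ± 1.57 in S1 and 7.45 ± 1.84 in S3 and was not called (0.90 ± 1.06, adjusted p = 0.655). Its spread within subsets followed the short and long arrays, and under the class block the change was -0.07, adjusted p = 0.838. Of 18 genes of erythropoietin signalling and survival, 4 rose and 2 fell (5 and 4 adjusted over the list alone). The survival genes Pim1 (1.25 ± 0.13, adjusted p = 0.00307) and Bcl2l1 (2.29 ± 0.36, adjusted p = 0.00784) rose, and, outside the naming rule and chosen after their values were seen, the feedback inhibitors Socs3 (2.80 ± 0.44, adjusted p = 0.00789) and Cish (1.92 ± 0.43, adjusted p = 0.0263). The signal transducer Stat5a (-2.74 ± 0.33, adjusted p = 0.00376) and the pro-apoptotic Bid (-2.78 ± 0.37, adjusted p = 0.00484) fell. This list's median log2 change was -0.32 and its mean -0.14, the median turned to 0.05 with median centring, and camera gave the upward direction without calling it (adjusted p = 0.167, or adjusted p = 0.688 with an estimated correlation). The class block gave 5 higher and 1 lower transcription factor genes, and 5 higher and 9 lower genes of the signalling list. Fas was too dim to be tested. Tal1 missed the threshold in 6 of 16 other planned fits (adjusted p from 0.00519 to 0.178, the highest with no intensity trend). Socs3 missed the threshold in 1 of 16 other planned fits (adjusted p from 0.00292 to 0.0586, the highest with the mean of its probe sets). Cish missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00184 to 0.108, the highest without S3 replicate 3).

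Genes of the G1 phase of the cell cycle moved both ways. Of 16 G1 cyclins and CDK inhibitors measured, 7 rose, 3 fell and 6 were not called (7 and 3 adjusted over the list alone). The antiproliferative gene Btg2 went from 3.83 ± 0.75 in S1 to 8.28 ± 0.32 in S3 (log2 change 4.45 ± 0.47 (SE), adjusted p = 0.00302) and the retinoblastoma gene Rb1 rose (1.60 ± 0.31, adjusted p = 0.0161), whereas Cdk6 (-4.00 ± 0.62, adjusted p = 0.00756) and Ccnd2 (-2.30 ± 0.40, adjusted p = 0.0111) fell. Outside the naming rule and chosen after their values were seen, the CDK inhibitor genes Cdkn2c (3.62 ± 0.72, adjusted p = 0.0170) and Cdkn2d (2.65 ± 0.58, adjusted p = 0.0233) rose. So did the inhibitor gene Cdkn1b (0.80 ± 0.18, adjusted p = 0.0264), the antiproliferative gene Btg1 (0.84 ± 0.22, adjusted p = 0.0443) and the cyclin gene Ccnd3 (2.32 ± 0.45, adjusted p = 0.0162), and Cdk4 fell (-0.54 ± 0.13, adjusted p = 0.0343). Cdkn1c was not above background on any S1 array and was not called (adjusted p = 0.179), but passed as higher with the class block (adjusted p = 0.00954). Of 24 mitosis genes 1 rose, Nusap1 (1.01 ± 0.19, adjusted p = 0.0138), and 5 had an unadjusted p under 0.05. Of 29 DNA replication genes none was called by limma and 1 had an unadjusted p under 0.05, E2f1 (0.94 ± 0.28, adjusted p = 0.0637), and Ccne2 was not called (0.83 ± 0.43, adjusted p = 0.259). With the class block 7 mitosis genes were higher and 1 lower, 2 replication genes higher, among them E2f1 (0.94, adjusted p = 0.00344), and 9 G1 genes higher and 3 lower. Over the other planned fits, 3 of which called E2f1 and 3 Ccne2, the adjusted p was 0.0279 to 0.614 and 0.0229 to 0.549. camera called G1 genes (adjusted p = 2.65e-05, or adjusted p = 0.356 with an estimated correlation), mitosis genes (adjusted p = 3.69e-07, or adjusted p = 0.397 with an estimated correlation) and replication genes (adjusted p = 6.06e-05, or adjusted p = 0.403 with an estimated correlation) higher. With the class block the median change of the replication list moved from 0.25 to -0.01 and that of the mitosis list from 0.70 to 0.22. Rb1 missed the threshold in 4 of 16 other planned fits (adjusted p from 8.40e-04 to 0.0694, the highest without S3 replicate 3). Ccnd2 missed the threshold in 2 of 16 other planned fits (adjusted p from 0.00940 to 0.222, the highest with the mean of its probe sets). Cdkn2c missed the threshold in 3 of 16 other planned fits (adjusted p from 0.00153 to 0.0685, the highest without S3 replicate 3). Cdkn2d missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00191 to 0.0914, the highest without S3 replicate 3). Cdkn1b missed the threshold in 7 of 16 other planned fits (adjusted p from 0.0133 to 0.109, the highest without S3 replicate 3). Btg1 missed the threshold in 10 of 16 other planned fits (adjusted p from 0.0208 to 0.174, the highest without S3 replicate 1). Ccnd3 missed the threshold in 5 of 16 other planned fits (adjusted p from 0.00112 to 0.0671, the highest without S1 replicate 1). Cdk4 missed the threshold in 11 of 16 other planned fits (adjusted p from 0.0282 to 0.851, the highest with median centring). Nusap1 missed the threshold in 6 of 16 other planned fits (adjusted p from 0.00126 to 0.117, the highest with the mean of its probe sets).

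Of 24 ribosome biogenesis genes measured 14 were lower, none was higher and 10 were not called (17 lower adjusted over the list alone). Nolc1 (log2 change -1.82 ± 0.18 (SE), adjusted p = 0.00302), Rrs1 (-1.23 ± 0.14, adjusted p = 0.00357), Ddx21 (-0.59 ± 0.09, adjusted p = 0.00602) and Gar1 (-1.29 ± 0.20, adjusted p = 0.00757) had the smallest adjusted p. The list's median log2 change was -0.74 relative to all genes, and negative under each scaling (camera adjusted p = 2.41e-07, or adjusted p = 0.356 with an estimated correlation). With the class block all 24 were lower. Of 43 ribosomal protein genes none was called by limma and 3 lower ones had an unadjusted p under 0.05. Rps25 (-1.15 ± 0.39, adjusted p = 0.0914) and Rpl14 (-0.47 ± 0.17, adjusted p = 0.113) had the smallest p, and the list's median was -0.04, which turned to 0.34 with median centring (camera upward, adjusted p = 0.272, or adjusted p = 0.815 with an estimated correlation). Of 14 glycolysis genes 6 fell, none rose and 8 were not called (1 higher and 8 lower adjusted over the list alone). Hexokinase 2, Hk2, fell from 8.01 ± 0.78 in S1 to 3.78 ± 0.23 in S3 (-4.24 ± 0.47, adjusted p = 0.00315), and Pgam1 (-1.29 ± 0.12, adjusted p = 0.00285), Pkm (-1.54 ± 0.32, adjusted p = 0.0209) and Aldoa (-0.44 ± 0.09, adjusted p = 0.0215) fell by less (camera adjusted p = 0.0994, or adjusted p = 0.632 with an estimated correlation). Of 23 chromatin modifier genes 7 fell, none rose and 16 were not called (1 higher and 8 lower adjusted over the list alone), with Kdm5b (-2.63 ± 0.43, adjusted p = 0.00903), Ehmt1 (-1.59 ± 0.32, adjusted p = 0.0192), Hdac2 (-0.97 ± 0.21, adjusted p = 0.0225) and Kat2a (-2.80 ± 0.64, adjusted p = 0.0269) as examples (camera adjusted p = 0.350, or adjusted p = 0.815 with an estimated correlation). Of 23 genes of the mitochondrial respiratory chain none was called by limma and 1 lower one had an unadjusted p under 0.05. Atp5a1 (-0.19 ± 0.07, adjusted p = 0.139) and Cyc1 (-0.33 ± 0.16, adjusted p = 0.240) came nearest, and the list's median of -0.09 turned positive under each other scaling (camera upward, adjusted p = 0.773, or adjusted p = 0.900 with an estimated correlation). The class block changed calls in these lists: 7 respiratory chain genes were lower, among them Cyc1 (-0.44, adjusted p = 0.00682), and 4 ribosomal protein genes, among them Rps25 (-1.33, adjusted p = 0.00263) and Rpl14 (-0.47, adjusted p = 0.0269). Under that block 4922 of all 11959 genes were lower. The respiratory chain and ribosomal protein medians were then 0.35 and 0.51 relative to all genes, so neither list lay lower than all genes. The class block also gave 1 higher and 10 lower glycolysis genes and 1 higher and 15 lower chromatin modifier genes. With this block camera called chromatin modifiers lower (adjusted p = 0.0392, or adjusted p = 0.318 with an estimated correlation). It called ribosomal proteins higher than all other genes (adjusted p = 0.0464, or adjusted p = 0.710 with an estimated correlation), though their own median was -0.04. Of other planned fits 1 called Rps25, that without S1 replicate 1 (adjusted p = 0.0492). Nolc1 missed the threshold in 2 of 16 other planned fits (adjusted p from 0.00237 to 0.0554, the highest with median centring). Rrs1 missed the threshold in 1 of 16 other planned fits (adjusted p from 0.00301 to 0.234, the highest with median centring). Ddx21 missed the threshold in 3 of 16 other planned fits (adjusted p from 0.00513 to 0.796, the highest with median centring). Gar1 missed the threshold in 1 of 16 other planned fits (adjusted p from 0.00254 to 0.114, the highest with median centring). Pgam1 missed the threshold in 1 of 16 other planned fits (adjusted p from 0.00181 to 0.157, the highest with median centring). Pkm missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00661 to 0.0813, the highest without S1 replicate 1). Aldoa missed the threshold in 8 of 16 other planned fits (adjusted p from 0.0181 to 0.941, the highest with median centring). Ehmt1 missed the threshold in 7 of 16 other planned fits (adjusted p from 0.0116 to 0.0780, the highest without S3 replicate 3). Hdac2 missed the threshold in 8 of 16 other planned fits (adjusted p from 0.0151 to 0.273, the highest with median centring). Kat2a missed the threshold in 5 of 16 other planned fits (adjusted p from 0.00400 to 0.221, the highest with the mean of its probe sets).

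**Figure D3:**
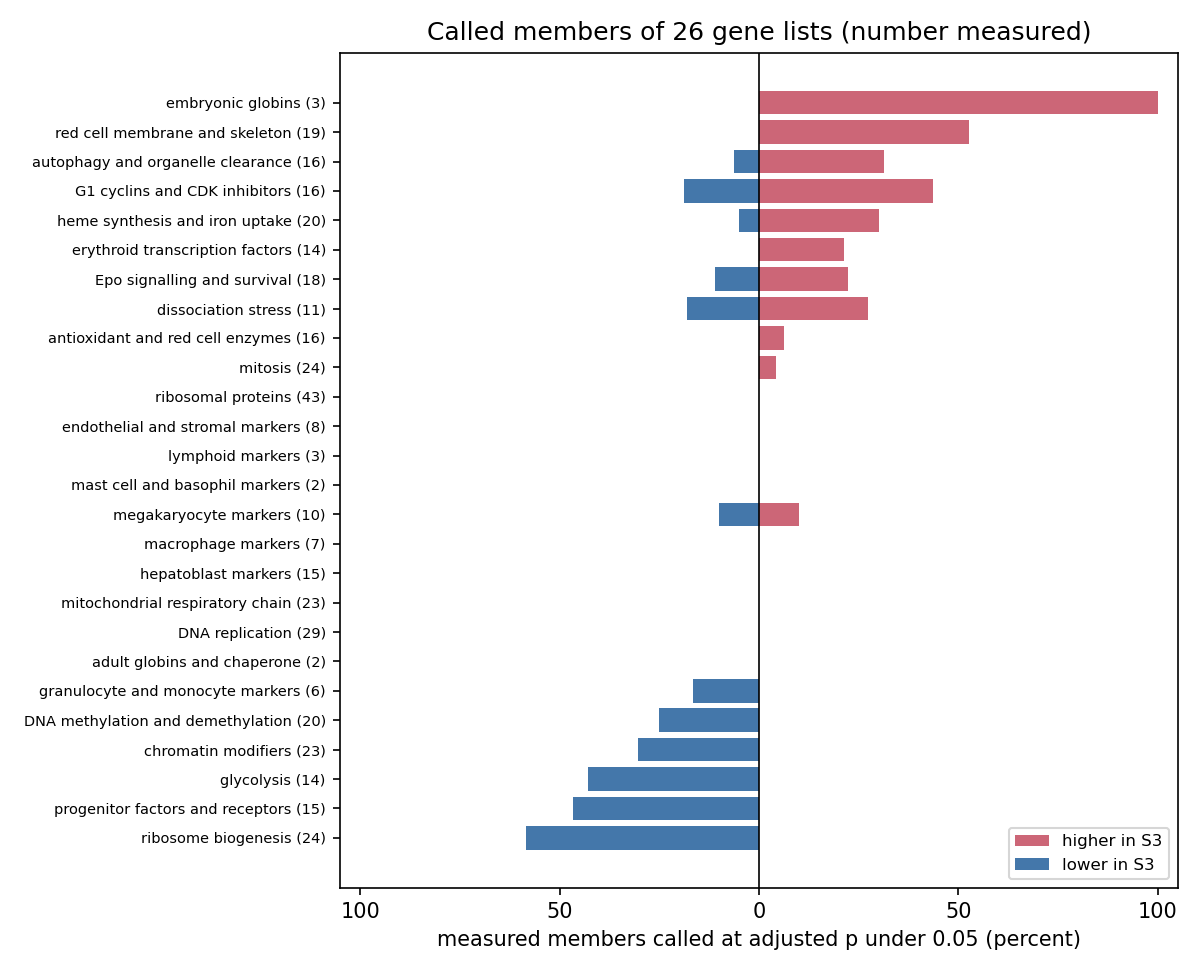
Share of each gene list's measured members called at an adjusted p under 0.05 (horizontal axis, percent), with red bars to the right for genes higher and blue bars to the left for genes lower in S3, for 26 lists (vertical axis, number of measured members in brackets). All 3 embryonic globin genes and 10 of 19 membrane genes were higher, and 14 of 24 ribosome biogenesis genes lower; lists with no bar had no called member.

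Of 16 genes of autophagy and organelle clearance 5 rose and 1 fell (8 and 2 adjusted over the list alone). The ubiquitin-conjugating enzyme genes Ube2l6 (log2 change 3.73 ± 0.33 (SE), adjusted p = 0.00279) and Ube2o (2.31 ± 0.50, adjusted p = 0.0223) and the autophagy gene Atg4d (1.68 ± 0.28, adjusted p = 0.00903) rose, and the autophagy gene Atg5 fell (-1.49 ± 0.34, adjusted p = 0.0272). Xpo7 (0.52 ± 0.12, adjusted p = 0.0288) and Ube2h (1.22 ± 0.29, adjusted p = 0.0291), outside the naming rule and chosen after their values were seen, also rose. camera called the list higher (adjusted p = 7.16e-06, or adjusted p = 0.356 with an estimated correlation). Of 16 antioxidant and red cell enzyme genes 1 rose, the biliverdin reductase gene Blvrb (0.90 ± 0.18, adjusted p = 0.0173), and camera called the list higher (adjusted p = 7.20e-04, or adjusted p = 0.356 with an estimated correlation). The class block gave 10 higher and 3 lower autophagy genes and 4 higher and 3 lower enzyme genes. Of 11 genes known to respond to tissue dissociation 3 rose and 2 fell (3 and 2 adjusted over the list alone). Dusp1 (2.01 ± 0.22, adjusted p = 0.00307) and Ier3 (2.24 ± 0.43, adjusted p = 0.0150) rose while Egr1 (-2.16 ± 0.48, adjusted p = 0.0243) and Hsph1 (-0.47 ± 0.09, adjusted p = 0.0177) fell. The immediate early gene Fos, outside the naming rule and chosen after its values were seen, was called at 5.08 ± 1.39, adjusted p = 0.0489. It was above background on 1 S1 array, and with values raised to background its log2 change was 2.16. The dissociation list's median was -0.25 and its mean 0.58, and the median was positive with median centring (0.12) and the trimmed mean (camera upward, adjusted p = 0.104, or adjusted p = 0.397 with an estimated correlation). With the class block camera called this list higher (adjusted p = 0.0289, or adjusted p = 0.174 with an estimated correlation). Ube2o missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00119 to 0.0904, the highest without S3 replicate 3). Atg5 missed the threshold in 9 of 16 other planned fits (adjusted p from 0.0214 to 0.316, the highest with the mean of its probe sets). Xpo7 missed the threshold in 8 of 16 other planned fits (adjusted p from 0.00763 to 0.364, the highest with the mean of its probe sets). Ube2h missed the threshold in 5 of 16 other planned fits (adjusted p from 0.0112 to 0.110, the highest without S3 replicate 1). Fos missed the threshold in 8 of 15 other planned fits (adjusted p from 0.0259 to 0.151, the highest without S1 replicate 1). Blvrb missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00305 to 0.0893, the highest with no intensity trend). Ier3 missed the threshold in 4 of 16 other planned fits (adjusted p from 0.00122 to 0.0708, the highest without S3 replicate 3). Egr1 missed the threshold in 4 of 16 other planned fits (adjusted p from 0.0178 to 0.0859, the highest without S3 replicate 3). Hsph1 missed the threshold in 7 of 16 other planned fits (adjusted p from 0.0143 to 0.921, the highest with median centring).

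Markers of other cells that a fetal liver holds were also read. Of 15 hepatoblast markers none was called by limma and 2 higher ones had an unadjusted p under 0.05, Ttr (log2 change 1.22 ± 0.39 (SE), adjusted p = 0.0768) and Apoa2 (1.22 ± 0.52, adjusted p = 0.166); both passed with each of the 3 other scalings, without S3 replicate 2 and with the class block (Ttr 1.10, adjusted p = 0.00816, Apoa2 0.97, adjusted p = 0.0493). camera called this list higher (adjusted p = 0.00650, or adjusted p = 0.456 with an estimated correlation), and with the class block its median change went from 0.87 to 0.28. Of 10 megakaryocyte markers 1 rose, Vwf (2.72 ± 0.60, adjusted p = 0.0244), and 1 fell, Gp5 (-2.26 ± 0.59, adjusted p = 0.0414), which was not above background on any S3 array and at least 2.48-fold lower there. Adjusted over the list alone 3 rose and 1 fell (camera higher, adjusted p = 0.00169, or adjusted p = 0.356 with an estimated correlation), and with the class block 4 were higher and 1 lower. Of 6 granulocyte and monocyte markers 1 fell, Prtn3 (-2.94 ± 0.54, adjusted p = 0.0127, or -2.44 with values raised to background; camera upward and fry downward, neither called, adjusted p = 0.421, or adjusted p = 0.743 with an estimated correlation). No member was called by limma, and none had an unadjusted p under 0.05, among 7 macrophage markers (Lyz2 0.76 ± 0.66, adjusted p = 0.528, Mrc1 0.59 ± 0.53, adjusted p = 0.544; camera upward, adjusted p = 0.116, or adjusted p = 0.356 with an estimated correlation), 8 endothelial and stromal markers (Stab2 -1.36 ± 0.66, adjusted p = 0.228, Col3a1 1.88 ± 1.30, adjusted p = 0.410, or -0.56 and 0.54 with values raised to background; camera upward, adjusted p = 0.167, or adjusted p = 0.397 with an estimated correlation) and 3 lymphoid markers (Igll1 0.93 ± 0.46, adjusted p = 0.239, Cd2 0.41 ± 0.66, adjusted p = 0.761; camera upward, adjusted p = 0.106, or adjusted p = 0.397 with an estimated correlation). The same held for 2 mast cell markers, Cma1 (-0.13 ± 0.51, adjusted p = 0.910) and Tpsb2 (-0.01 ± 0.63, adjusted p = 0.993). With the class block camera called the macrophage list higher (adjusted p = 0.0324, or adjusted p = 0.178 with an estimated correlation). It also called the endothelial and stromal list higher (adjusted p = 0.0333, or adjusted p = 0.267 with an estimated correlation). Vwf missed the threshold in 4 of 15 other planned fits (adjusted p from 0.00415 to 0.0948, the highest without S3 replicate 3). Gp5 missed the threshold in 9 of 15 other planned fits (adjusted p from 0.0327 to 0.124, the highest without S1 replicate 2). Prtn3 missed the threshold in 2 of 15 other planned fits (adjusted p from 0.00870 to 0.0618, the highest without S1 replicate 1).

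camera with a preset inter-gene correlation of 0.01 called 11 of 24 lists higher and 2 lower than all other genes, in S3 against S1. With the correlation estimated per list it called 0, with 2 lists at an unadjusted p under 0.05 and a lowest adjusted p of 0.356. fry, which asks only whether the genes of a list move one way on balance, called embryonic globins and heme genes higher and progenitor and ribosome biogenesis genes lower (adjusted p = 0.0339, 0.0449, 0.0339 and 0.0339). The reference probe sets differed between S3 and S1 by a log2 difference of 0.10 for 18S ribosomal RNA, -0.15 for Gapdh and -0.01 for Actb.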

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

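The test reported here was chosen after seeing the data. Probe sets with several gene symbols or none were outside the comparisons: 67 of 4594 bright enough to test passed limma's adjusted p of 0.05 between S3 and S1, 19 higher and 48 lower. They are unnamed here, and no explanation was tested.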

How the results depend on the processing

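The settings with the 5' class, and those with the long or short arrays alone, were added after seeing the data. Signal over background limits folds: 64 called genes had no array of one subset above it, and their size is a lower bound. A simulated log2 change of 1 was recovered for 12% of genes, but with only 200 genes changed, so that the cut on p was stricter than in the data. Median centring, quantile normalization and the trimmed mean gave 595, 695 and 612 higher genes, and 586, 572 and 525 at least 2-fold higher; median centring gave 771 lower and 768 at least 2-fold lower, and the mean of probe sets 991 lower. The class block gave 695 higher, 4922 lower, 391 and 3042 at least 2-fold; the covariate 641, 4585, 3007 at least 2-fold lower and 4 lists lower; the class block with median centring 2488 higher and 1808 lower, 1070 and 1257 at least 2-fold, the 1 setting with more genes higher than lower; the long arrays 617, 4151, 393 and 2726; the short arrays 2601 and 2371 lower. Leaving out 1 array gave 119 to 370 higher and 541 to 1273 lower genes, 109 to 333 and 493 to 1075 at least 2-fold. An estimated correlation called 0 lists higher and 0 lower, and fry 2 higher. Camera has no robust option, so the robust trend was not run for lists. The cause of these shifts was not tested. Median centring kept 941 of 1835 calls, quantile normalization 1288, the trimmed mean 1315 and the class block all 1835, and none of these 4 fits called a gene in the opposite direction, although 5 calls changed sign without being called under median centring and 1 under quantile normalization. The class block with median centring called 1414 of the 1835, 13 of them in the opposite direction, and 104 of the 1835 changed sign.

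The replicate block (paired by replicate number) gave 412 higher and 1897 lower genes, 339 and 1515 at least 2-fold, and 11 and 2 lists. The labels do not say that a number marks a day. Same-numbered arrays deviated from their subset means with correlations of -0.19, 0.36 and 0.43 across genes. The first pair joins a short and a long array, and the 4 other such pairs had -0.58 to -0.21; the 2 others of equal class had 0.28 and 0.40. A shared day is thus not excluded.

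Of 75 called named genes, 49 kept their call and direction in all 6 fits that left out 1 array, 51 in all other planned fits that tested them, 69 in all added ones and 41 in all of these. The log2 change turned sign for these genes, 4 of them called (Ddx21, Aldoa, Hsph1 and Cdk4): with class block Hbb-b2 -0.0260, Dnmt1 -0.16, Tet3 -0.50, Mbd4 -0.11, Epor -0.0714, with covariate Hbb-b2 -0.0271, Cd2 -0.0131, Dnmt1 -0.19, Tet3 -0.49, Mbd4 -0.14, Epor -0.13, with long arrays Hbb-b2 -0.0505, Cd2 -0.84, Col3a1 -0.35, Dnmt1 -0.0360, Tet3 -0.44, Mbd4 -0.13, Gata1 0.0277, with short arrays Hbb-b2 -0.00148, Lyz2 -0.70, Mrc1 -0.11, Tpsb2 0.24, Dnmt1 -0.28, Tet3 -0.57, Mbd4 -0.10, Klf1 -0.0390, Epor -0.31, with class block with median centring Ddx21 0.0634, Aldoa 0.19, Atp5a1 0.49, Cyc1 0.25, Hsph1 0.23, Cma1 0.58, Tpsb2 0.57, Rpl14 0.21, Gata1 0.67, Cdk4 0.13, with median centring Atp5a1 0.19, Cyc1 0.0461, Cma1 0.25, Tpsb2 0.36, Gata1 0.25, with trimmed mean Atp5a1 0.0854, Cma1 0.14, Tpsb2 0.26, Gata1 0.15, with quantile normalization Cma1 0.0547, Tpsb2 0.21, Gata1 0.0294, with 25th percentile added Tpsb2 0.0230, and, leaving out 1 array, Hbb-b2 -0.0190 to 0.0550, Cma1 -0.36 to 0.15, Tpsb2 -0.51 to 0.50, Dnmt1 -0.0483 to 0.59, Tet3 -0.47 to 0.61. Of the 4 called genes that turned sign, Cdk4 was named outside the rule and is not among the 75. The cause of these turns was not tested.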

Other observations

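The interferon list and the tests of spread, scaling, class, signal share and splits were chosen after the result was seen.

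The cholesterol, amino acid, proteasome and interferon gene lists were added after the data were examined, each as a hypothesis. Of 16 interferon-stimulated genes 1 was higher and 2 lower in S3; the median log2 change was 0.30 ± 0.53 (SE) relative to all genes, with p = 0.598 with an estimated correlation. The cholesterol synthesis list (18 genes, 0 higher, 2 lower) had 0.22 ± 0.24 (SE) relative to all genes, with p = 0.818 with an estimated correlation, the amino acid synthesis and transport list (16 genes, 0 higher, 4 lower) 0.35 ± 0.27 (SE) relative to all genes, with p = 0.919 with an estimated correlation and the proteasome list (25 genes, 0 higher, 1 lower) 0.31 ± 0.08 (SE) relative to all genes, with p = 0.725 with an estimated correlation. The standard errors of these medians are taken over the genes of a list, which were read on the same arrays. The genes are not independent (estimated correlation 0.26 for interferon to 0.50 for proteasome genes), so these errors are too small. Predicted were a rise of interferon and proteasome genes and a fall of cholesterol and amino acid genes. None of the 4 predictions was met, since each needed a median beyond 0.5 and p under 0.05. The bounds against them, a median on the other side of 0, were written beforehand except for the interferon list. The interferon and proteasome medians lay on the predicted side only relative to all genes, and leave these predictions open. Before centring these medians were -0.0330 and -0.0275. Of the interferon estimates 7 lay above 0 and 9 below, and of the proteasome estimates 12 above and 13 below. The cholesterol and amino acid medians met their bounds, and both predictions are left open only by allowances set after the values were seen. The cholesterol median lay within its error of 0. The amino acid median lay above 0 by more than its error, but that error is too small to decide its side. Before centring 8 estimates lay above 0 and 8 below, called or not, and of the called members 4 were lower and 0 higher. That split was the allowance for this list, and its bound was met as written.

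Arrays of one subset spread mainly along 1 axis. Same-numbered arrays had a lowest correlation of deviations of -0.19, for replicate 1, whose S1 array is short and S3 array long and which lay at -0.25 and 0.31 on that axis. This argues against a preparation shared by equal replicate numbers as the cause of this axis only. A lesser effect of such a preparation stays open, since -0.19 was the highest of the 5 pairs that join a short and a long array. Shorter cDNA on 3 arrays may account for the spread: short and long arrays lay apart on the first component by a gap of 0.56, and the Gapdh and Tfrc controls, not used to define the classes, also read lower at the 5' end on all 3 short arrays. The classes cross the subsets, and no biological explanation was tested.

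More genes were lower than higher in S3 in every setting tried but the class block with median centring (2488 higher, 1808 lower). The hybridisation spike-ins differed by 0.0565 ± 0.0987 (SE, log2) against a median gene change of -0.33. This argues against an offset of that size left by the reference scaling only if the median is taken as exact. The median was -0.14 without S1 replicate 3 and -0.45 without S1 replicate 2, and that spread is not in the error. Equal spike-in amounts on all arrays are also assumed, which no label states. Such an offset is therefore not excluded. Unequal numbers of short arrays are argued against because the class block moved the median to -0.54, further from 0. A few transcripts taking most of the signal cannot be told apart from other causes, since the share of the 100 brightest probe sets would lower the rest by only -0.0123 but their readings lie near the top of the scale, where a rise may not be read in full. The subset itself and embryo age stay open and untested.

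The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. A count as large as 302 higher genes came from 2 of 10 splits (highest other 741), and as large as 1533 lower genes from 1 (highest other 741); for at least 2-fold these were 2 for 258 and 1 for 1264 (highest other 682). The split into short and long arrays gave the 741 and 682, and with the class as a block the real counts were 695 higher and 4922 lower. For lists, 3 of 10 splits gave 11 called one way and 10 of 10 gave 2 (highest other 11), and 3 splits other than the real one called 13 lists in all, as many as it did.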
